A study of Homo sapiens with 9 samples.

How the data were processed

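RNA-seq data from 9 libraries of THP-1 cells were analysed. THP-1 is an established human acute myeloid leukaemia line with a monocytic phenotype that carries the KMT2A-MLLT3 fusion, also written MLL-AF9. Per the labels' protocols, cells were spinoculated with lentivirus produced in 293T cells, selected with puromycin from 24 hours, and harvested for RNA 48 hours after spinoculation, and polyadenylated RNA was sequenced. The labels put 3 libraries in each of 3 groups: a non-targeting control shRNA and the NFATC2 shRNAs shRNA-143 and shRNA-146. The series describes the replicates as biological, but nothing in the sources used here says that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

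The authors deposited a table of raw counts per gene for 58735 Ensembl gene identifiers, all of which are in GENCODE release 29, with no replicates pooled. The submitters' processing notes name fastp, STAR 2.5, featureCounts and DESeq2, and the hg38 genome build, without saying what each was used for. Whether counting used strand, and how reads in overlapping genes were treated, is not given in the sources used here. Counts of genes that overlap another gene or have near-identical copies, such as ribosomal protein genes with processed pseudogenes, are therefore uncertain. The authors also deposited a comparison table for each shRNA against control, which lists genes with a summed count of at least 2 over its 6 libraries. The normalized signal columns in those tables are counts that the authors divided by 1 size factor per library, as a constant ratio to the counts shows. Their FPKM columns were proportional to counts divided by the deposited gene length in every library. The deposited log2 fold changes and p-values are the authors' own, and the test that gave them is not stated in the file headers. An adjusted p of 1 stands in 7857 and 10640 of the listed genes. Only the counts, the gene annotation with its gene lengths, and the fold changes and p-values of those tables were used here. Counts in the comparison tables were identical to those of the count table in all listed genes.

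Library totals ran from 40047459 to 44669709 counts, and every entry of the count table named a gene. Differences between libraries of a group were far larger than counting noise, with a chi-square per degree of freedom between 22.4 and 432, so no library repeated another. Genes were kept by edgeR's filterByExpr, which left 14975 genes that held at least 99.9% of the counts of every library. Counts were scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood test (glmQLFit, robust, and glmQLFTest) on R 4.3.3, with all 9 libraries in a single fit of 3 group means and 6 residual degrees of freedom. P-values were adjusted over all tested genes by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were each shRNA against control, the mean of both shRNAs against control, and shRNA-146 against shRNA-143. Standard errors are those implied by the log2 fold change and its F statistic. CPM values are after TMM scaling.

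The titles number the replicates 1 to 3 in each group, and the labels do not say what a number shares. Deviations from the group means were therefore compared between groups, on log2 CPM with a prior count of 2. All 9 pairs of libraries that share a number had a positive correlation, from 0.252 to 0.758, against -0.678 to 0.535 for libraries with different numbers, and 9 of 9 libraries had their best match in the other groups at their own number. The first principal component held 58.1% of the variance and set the libraries numbered 1 apart. All pairs that share a number met the criterion of a correlation over 0.1, which does not use the calls. Pairs across groups of a library numbered 2 and a library numbered 3 met it too, at 0.101 to 0.535. The criterion thus sets apart only the libraries numbered 1. Between numbers 2 and 3 the pairing rests on the best matches, and margins could be thin. Control replicate 2 had 0.539 with shRNA-146 replicate 2 and 0.520 with shRNA-146 replicate 3. The pairing comes from the data, since the labels give only the numbers. The fit with the replicate number as a block (4 residual degrees of freedom) is therefore given beside the fit without it.

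Gene lists were 34 sets fixed before the data were examined, covering pathways, lineage markers and markers of other cell types. Lists with at least 5 tested members were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01, and adjusted over the lists within a comparison. Camera with an estimated correlation, camera on ranks and fry, which tests whether a list's genes move on balance in a single direction, were alternatives. Calls of list members are given both over all genes and adjusted over the list alone.

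The genes named were also chosen by a rule fixed before the data were examined. For both shRNAs, the rule took the 12 genes up and the 12 down with the largest value of the smaller absolute log2 fold change, among protein-coding genes past the threshold in both comparisons with the same sign, a mean of at least 4 CPM, and no overlap between any shRNA library and any control library. Symbols of clone-based names were left out. For each shRNA, and for shRNA-146 against shRNA-143, it took the 5 up and 5 down with the largest fold change under the same conditions. For each list described, it took up to 4 members with the smallest p for the mean of both shRNAs. MYC, HOXA9, MEIS1 and CDKN1A were named whatever their p. Some genes that the rule takes are not reported here. NECAP1 and PPP1R14C, which passed for shRNA-146 against shRNA-143 without the block, fall outside the rule and were named after their values were seen. After the data were seen, the same rule was also applied to the fit with the block, since few genes passed without it.

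Both fits were tested on simulated data, in 5 runs that changed 200 genes for shRNA-143 over a mean of 14740 tested genes. Counts were drawn gene by gene from means fitted with the replicate number alone and from the dispersions of the fit with the block. The draws thus follow the model of that fit, and do not test replicate effects that differ between groups. Without the block, 0.205% of log2 changes of 1 and 39.9% of log2 changes of 2 were recovered, with 0 false calls. With the block, 66.0% and 91.2% were recovered, with a mean of 10 false calls. In 20 simulations of unchanged groups, 0.456% of genes had an unadjusted p under 0.05 without the block and 4.80% with it.

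Alternatives fixed in advance were median-of-ratios and upper quartile scaling, no scaling, no filter and a stricter filter on low counts (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, a fit that is not robust, a fit of only the groups compared, an absolute log2 fold change of at least 1, the replicate block, and leaving out each library in turn. Chosen after seeing the data were a correction of each library for a smooth trend in gene length and GC content (mgcv 1.9.3), the same with the block, leaving out the 3 libraries numbered 1, and all alternatives repeated in the fit with the block. The GC content of 14972 of the tested genes came from the reference annotation.

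A scan of 3' UTRs, also chosen after seeing the data, compared genes that carry each of 16284 words of 7 bases in their longest annotated 3' UTR with genes that lack it. It used the log2 fold changes of the blocked fit over 9454 genes, with a z-score that allows for the 3' UTR's length and composition, the gene length and the expression level. Its bound came from the largest score in each of 200 permutations of the genes. It ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. In its own simulated test, 5 of 5 planted words were found.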

Results

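RNA from THP-1 cells, a human acute myeloid leukaemia line with the MLL-AF9 fusion, was sequenced 48 hours after transduction with lentivirus carrying a control shRNA or either of the NFATC2 shRNAs named shRNA-143 and shRNA-146, with 3 libraries per group. Total counts ran from 40047459 in control replicate 3 to 44669709 in shRNA-146 replicate 2, and genes with a count from 18485 in shRNA-146 replicate 1 to 21723 in shRNA-146 replicate 3. Libraries that share a replicate number deviated alike, though numbers 2 and 3 were not clearly set apart. Counts of genes are therefore given without and with the number as a block. Gene values are log2 fold changes ± SE from the fit with the block, with n = 3 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test unless stated otherwise.

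The first question was how far each shRNA lowered its target. NFATC2 (ENSG00000101096, chromosome 20, 51386957 to 51562831, minus strand, hg38) encodes a transcription factor that calcineurin activates by dephosphorylation. It stood at 22.5 ± 8.56 CPM (SD, n = 3) in control, 5.28 ± 3.29 with shRNA-143 and 6.24 ± 3.44 with shRNA-146. With the block NFATC2 was 4.83-fold lower with shRNA-143 (-2.27 ± 0.24, adjusted p = 0.00168) and 3.89-fold lower with shRNA-146 (-1.96 ± 0.23, adjusted p = 0.00435). Within a replicate number it was at 11.7%, 26.8% and 25.4% of control with shRNA-143 and at 20.5%, 24.3% and 34.4% with shRNA-146. Control replicate 1 held 12.7 CPM, against 27.6 and 27.4 in the other control libraries. Without the block the changes were -2.09 ± 0.64 (adjusted p = 0.497) and -1.85 ± 0.63 (adjusted p = 0.464), short of the threshold. The difference between the shRNAs, 0.31 ± 0.23, did not pass (adjusted p = 0.713).

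**Figure D1:**
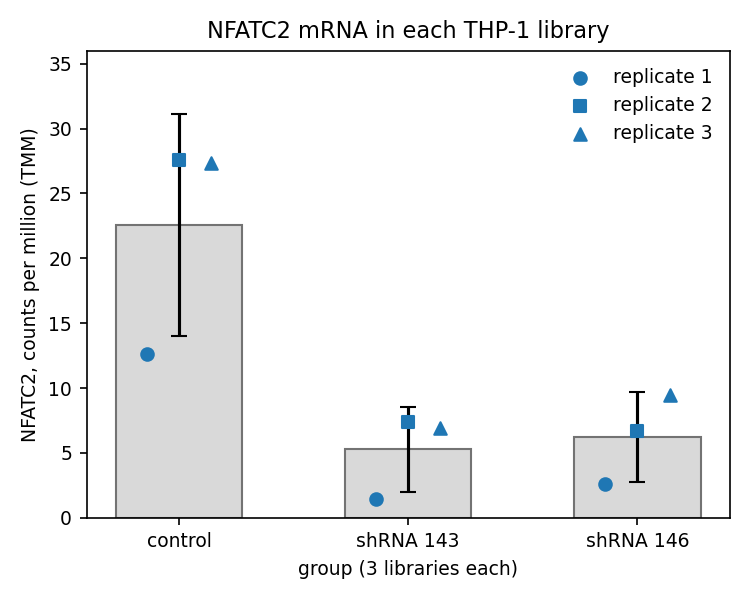
NFATC2 in CPM after TMM scaling, by group, with 1 point per library, bars at the mean of 3 libraries and error bars of 1 SD. Every knockdown library lay below every control library, with means of 22.5 in control, 5.28 with shRNA-143 and 6.24 with shRNA-146.

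With shRNA-143, SHISA5, an endoplasmic reticulum and nuclear membrane protein linked to p53-dependent apoptosis, was the named gene with the largest change against control. SHISA5 (ENSG00000164054, chromosome 3, 48467798 to 48504826) fell from 183 ± 30.4 CPM in control to 24.2 ± 4.56 (SD, n = 3), a log2 fold change of -2.92 ± 0.16 (adjusted p = 2.89e-05). ETFRF1, a regulator of the mitochondrial electron transfer flavoprotein, fell by 2.67 ± 0.25 on the log2 scale (adjusted p = 0.00111) and DGUOK, the mitochondrial deoxyguanosine kinase, by 2.10 ± 0.15 (adjusted p = 0.000163). Also lower were ELL2, an elongation factor of RNA polymerase II, at -1.99 ± 0.22, the haematopoietic transcription cofactor LMO2 at -1.75 ± 0.13, and the neddylation enzyme UBE2F at -2.08 ± 0.26. Among the genes that rose, TULP3, a ciliary trafficking protein, gained 2.49 ± 0.21, the GTPase RABL6 1.94 ± 0.30, the SLAM family receptor CD84 1.76 ± 0.24, the scaffold AHNAK 1.65 ± 0.27 and the endosomal protein SNX16 1.52 ± 0.19. Except for SHISA5, TULP3, ETFRF1, DGUOK, ELL2 and LMO2, with adjusted p-values from 0.00214 to 0.0451, these genes did not pass without the block. ETFRF1, DGUOK, ELL2, UBE2F, TULP3, RABL6 and SNX16 have exons that overlap those of other genes, so their counts are uncertain.

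With shRNA-143, 474 of 14975 genes passed with the block, 239 up and 235 down, and 7 without it, 1 up and 6 down, with 1019 at an unadjusted p under 0.05. Scaling by library size alone gave 267 up and 147 down with the block and 6 up and 10 down without it. The length and GC correction with the block gave 667 up and 819 down. With the block the count without replicates 1, 2 and 3 of shRNA-143 was 114, 60 and 55, of shRNA-146 2099, 237 and 1050, and of control 144, 58 and 73. Without the block these counts were, in the same order, 4, 1, 1, 28, 2, 6, 1, 4 and 1.

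With shRNA-146, YES1, a SRC family kinase, and OCRL, an inositol phosphatase of endosomes, rose beside TULP3. YES1 rose from 14.1 ± 1.46 to 54.5 ± 8.96 CPM (SD, n = 3), a log2 fold change of 1.95 ± 0.15 (adjusted p = 0.000701), OCRL by 1.69 ± 0.15 (adjusted p = 0.000713) and TULP3 by 2.52 ± 0.21 (adjusted p = 0.000713). HMOX1, the inducible haem oxygenase, rose by 1.58 ± 0.35 and the GTPase RAB12 by 1.55 ± 0.17. Lower were SVIP, an inhibitor of endoplasmic reticulum-associated degradation, at -1.68 ± 0.20, the RNA exosome subunits EXOSC6 at -1.58 ± 0.14 and EXOSC1 at -1.56 ± 0.17, the adaptor HSH2D at -1.57 ± 0.22, and DNAJC19, a component of mitochondrial protein import, at -1.49 ± 0.25. Of these, TULP3, YES1, OCRL, RAB12 and EXOSC6 also passed without the block, with adjusted p-values from 0.0273 to 0.0488. Exons of HSH2D overlap RAB8A and those of DNAJC19 SOX2-OT, and TULP3, YES1, RAB12 and SVIP also overlap other genes.

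With shRNA-146, 662 of 14975 genes passed with the block, 369 up and 293 down, and 5 without it, 4 up and 1 down, with 1319 at an unadjusted p under 0.05. Scaling by library size alone gave 679 up and 156 down with the block and 2 up and 0 down without it, and median-of-ratios scaling without the block gave 3 up and 0 down. The length and GC correction with the block gave 781 up and 929 down. With the block the count without replicates 1, 2 and 3 of shRNA-143 was 563, 228 and 307, of shRNA-146 1745, 270 and 329, and of control 140, 27 and 89. In the same order and without the block they were 2, 0, 0, 3, 0, 0, 0, 0 and 0.

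The use of 2 constructs asks which genes moved with both. TULP3 (ENSG00000078246, chromosome 12, 2877223 to 2941140) went from 1.97 ± 0.407 CPM in control to 11.2 ± 2.73 and 11.3 ± 1.80 (SD, n = 3 each), and was the gene that passed in both comparisons without the block, with adjusted p-values of 0.0211 and 0.0273. With the block, genes that rose with both included OCRL by 1.30 ± 0.15 and 1.69 ± 0.15, SNX16 by 1.52 ± 0.19 and 1.49 ± 0.19, the autophagy lipid scramblase ATG9A by 1.18 ± 0.17 and 1.41 ± 0.18, and RUFY2 by 1.16 ± 0.23 and 1.40 ± 0.23, with shRNA-143 and shRNA-146 in that order. YES1 rose by 1.35 ± 0.15 and 1.95 ± 0.15, AHNAK by 1.65 ± 0.27 and 1.77 ± 0.28, CD84 by 1.76 ± 0.24 and 1.35 ± 0.24, and IGF2BP3, an mRNA-binding protein of leukaemia cells, by 1.24 ± 0.26 and 1.27 ± 0.26. MGAT4B, a glycosyltransferase, the interferon-inducible GTPase GBP3 and the bromodomain protein BRWD3 rose by 1.11 to 1.28. All of these genes passed with the block in both comparisons, with adjusted p-values up to 0.0338.

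Among genes lower with both, EXOSC6 fell by 1.18 ± 0.13 and 1.58 ± 0.14, the GTPase RAC3 by 1.63 ± 0.27 and 1.29 ± 0.27, COMTD1 by 1.20 ± 0.21 and 1.33 ± 0.21, and HSH2D by 1.20 ± 0.22 and 1.57 ± 0.22. The cytoskeletal adaptor PSTPIP1 fell by 1.14 ± 0.19 and 1.05 ± 0.19, DHCR7, which makes cholesterol in its last step, by 1.43 ± 0.14 and 0.82 ± 0.14, and the RNA-binding protein TSN by 1.05 ± 0.14 and 0.84 ± 0.14. SPNS3 fell by 0.94 ± 0.18 and 1.48 ± 0.18, and the complement inhibitor CD59 by 0.80 ± 0.18 and 1.08 ± 0.19. C1RL, the methionine sulfoxide reductase MSRB1 and the methyltransferase EEF1AKMT4 fell by 0.84 to 1.09. Adjusted p-values with the block were at most 0.0426. Of the genes named for both, MGAT4B overlaps SQSTM1, IGF2BP3 MALSU1, RUFY2 HNRNPH3 and C1RL C1R, which leaves their counts uncertain. The same holds for TULP3, SNX16, ATG9A, YES1, GBP3, HSH2D, SPNS3, CD59 and EEF1AKMT4, which overlap other genes.

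Of the genes that passed with both shRNAs in the same direction, 149 were up and 51 down with the block, and 1 up and 0 down without it, where 458 genes had an unadjusted p under 0.05 in both with the same sign. Scaling by library size alone gave 196 up and 24 down with the block, and the length and GC correction with the block 364 up and 281 down. With TMM scaling, the block and no such correction, another 4 genes passed in opposite directions, and independent lists of these sizes would share 5.89 up and 4.60 down. Across genes, which are not independent replicates, the shRNAs' log2 fold changes had a Pearson r of 0.690 and a Spearman correlation of 0.689 with the block, and 0.702 and 0.703 without it. Unchanged groups sharing simulated controls, drawn under the model of the fit with the block, gave r = 0.508 in both fits. The covariance was 0.158 against a simulated 0.0460 with the block, a difference of 0.112, and 0.162 against 0.0473, a difference of 0.115, without it. The same sign was seen in 77.0% of genes with the block, against a simulated 66.9%, and at most 1 gene passed in both comparisons in 20 simulations. The 3 control libraries could not be parted into groups of at least 2, so part of the excess may come from the shared controls. With the block the count of 200 became 60, 22 and 19 without replicates 1, 2 and 3 of shRNA-143, 878, 68 and 172 of shRNA-146, and 36, 11 and 26 of control. Without the block the count of 1 became, in the same order, 1, 0, 0, 3, 0, 0, 0, 0 and 0.

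**Figure D2:**
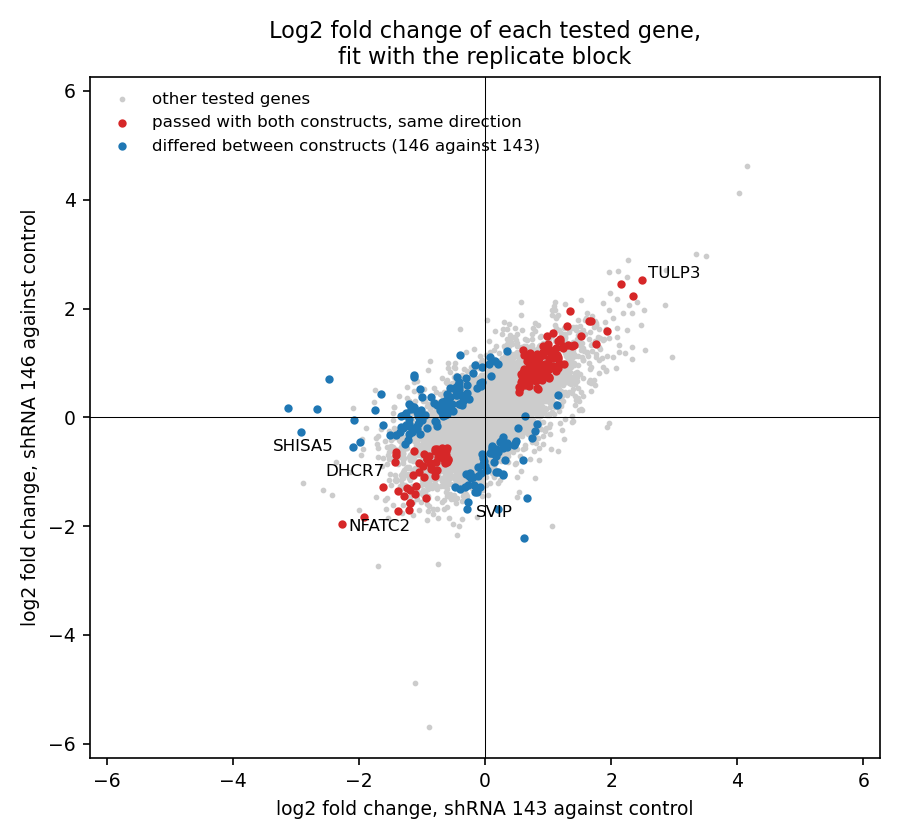
Log2 fold change against control of each of 14975 tested genes with shRNA-143 (horizontal axis) and shRNA-146 (vertical axis), from the fit with the replicate block; red points passed with both in the same direction and blue points differed between the shRNAs. The 200 red points include TULP3 at 2.49 and 2.52 and NFATC2 at -2.27 and -1.96. Blue marks those of the 179 genes that differed that are not red, among them SHISA5 at -2.92 and -0.26.

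For the mean of both shRNAs against control, 859 genes passed with the block, 447 up and 412 down, and 5 without it, 3 up and 2 down, with 1399 at an unadjusted p under 0.05. Scaling by library size alone gave 664 up and 194 down with the block and 3 up and 1 down without it, and moved the median of all genes from 0.01 to 0.12. The balance turned with other settings of the block: 43.1% of calls were up with upper quartile scaling, and the length and GC correction gave 955 up and 1263 down. With the block the count without replicates 1, 2 and 3 of shRNA-143 was 647, 204 and 216, of shRNA-146 3075, 499 and 912, and of control 154, 14 and 38, and in the same order without the block 2, 0, 0, 5, 0, 0, 0, 0 and 0. Of the 986 tested members of any gene list, 38 were up and 64 down with the block. Without it edgeR passed 0, with 48 up and 63 down at an unadjusted p under 0.05, against 7 up and 7 down by DESeq2 and 0 by limma-voom.

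Ribosomal protein, mitochondrial ribosome and nuclear-encoded oxidative phosphorylation transcripts lay below control with both shRNAs. The 79 ribosomal protein genes had a median log2 fold change of -0.39, and 8 fell and 0 rose over all genes, against 51 and 0 adjusted over the list alone. Among those short of the threshold over all genes, RPS25 stood at -0.62 ± 0.17 and RPL41 at -0.70 ± 0.22 (adjusted p = 0.0596 and 0.0869). Of 75 mitochondrial ribosome genes, with a median of -0.39, 19 fell and 0 rose, against 36 and 0 adjusted over the list alone, among them MRPL34 by 0.76 ± 0.15, MRPS12 by 0.65 ± 0.15, MRPS26 by 0.54 ± 0.13 and MRPL2 by 0.50 ± 0.12. Of 76 nuclear-encoded oxidative phosphorylation genes, with a median of -0.33, 7 fell and 1 rose, against 18 and 1 adjusted over the list alone. The ATP synthase subunit ATP5ME fell by 0.94 ± 0.18 and cytochrome c, CYCS, by 0.58 ± 0.11, while COX7C rose by 0.87 ± 0.15, and NDUFB10 stood at -0.48 ± 0.14 (adjusted p = 0.0707). Library size scaling brought the oxidative phosphorylation median to -0.21. The 13 mitochondrially encoded genes had a median of -0.10, which that scaling turned to 0.02, and within a replicate number medians of 0.50 and 0.31 in replicate 1 and of -0.68 to -0.09 in the others. Camera gave the ribosomal, mitochondrial ribosome and nuclear-encoded lists adjusted p-values of 2.31e-18, 1.61e-14 and 1.30e-11 with the block, and adjusted p = 0.553, 0.539 and 0.578 with an estimated correlation. Without the block the medians were -0.36, -0.38 and -0.32, with camera adjusted p-values of 2.44e-12, 9.79e-12 and 6.88e-09, and adjusted p = 0.636 for each with an estimated correlation. Their genes were short, with median lengths of 3109, 2549 and 2545 bases against 4550 over all genes, and of 5 equal bins of all genes by length, the shortest had a median of -0.22 and the longest of 0.19.

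Nucleolar MYC target genes, 58 tested, had a median of -0.23, with 6 down and 0 up over all genes and 13 down and 1 up adjusted over the list alone. NOP16 fell by 0.50 ± 0.11 and RRP9 by 0.41 ± 0.10, both ribosome assembly factors, while BYSL stood at -0.36 ± 0.11 (adjusted p = 0.0716). MYC itself was at -0.08 ± 0.10 (adjusted p = 0.652), a direction that library size scaling turned to 0.03. Granulocyte and promyelocyte genes, 18 tested, had a median of -0.27, with 5 down and 0 up, and 8 down and 0 up adjusted over the list alone. They were short, with a median length of 1668.5 bases against 4550 over all genes, and the shortest bin of all genes had a median of -0.22. Their fall is thus not set apart from the trend with length. CEBPE, a regulator of late granulocyte maturation, fell by 1.25 ± 0.22, the defensin DEFA4 by 0.78 ± 0.14, myeloperoxidase, MPO, by 0.71 ± 0.11 and SERPINB1 by 0.44 ± 0.12. With library size scaling the medians of the MYC targets and granulocyte genes were -0.12 and -0.15. Camera adjusted p-values were 3.21e-05 for the MYC targets and 0.000314 for the granulocyte genes with the block, and adjusted p = 0.143 and 0.332 with an estimated correlation. Without the block they were 0.000194 and 0.0101, and adjusted p = 0.328 and 0.504 with an estimated correlation.

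Interferon-stimulated genes lay above control. Of 44 tested, with a median of 0.25, 7 rose and 0 fell, against 12 and 2 adjusted over the list alone. SAMD9L rose by 1.13 ± 0.19, the death ligand TNFSF10 by 0.64 ± 0.16, the transcription factor IRF1 by 0.59 ± 0.13 and the ISG15 ligase HERC5 by 0.56 ± 0.14. The camera adjusted p was 0.00108 with the block and 0.000760 without it, and adjusted p = 0.452 and 0.432 with an estimated correlation. The 32 tested NF-kB and inflammatory genes had a median of 0.12, with 3 up and 0 down, and 4 up and 0 down adjusted over the list alone, and library size scaling raised the median to 0.24. They passed without the block (adjusted p = 0.0401, and adjusted p = 0.636 with an estimated correlation) and not with it (adjusted p = 0.0742). NFKBIZ rose by 1.12 ± 0.25 and BCL3 by 1.13 ± 0.28, both nuclear IkB proteins, and BIRC3, an apoptosis inhibitor at 0.129 CPM in control, by 1.84 ± 0.45.

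**Figure D3:**
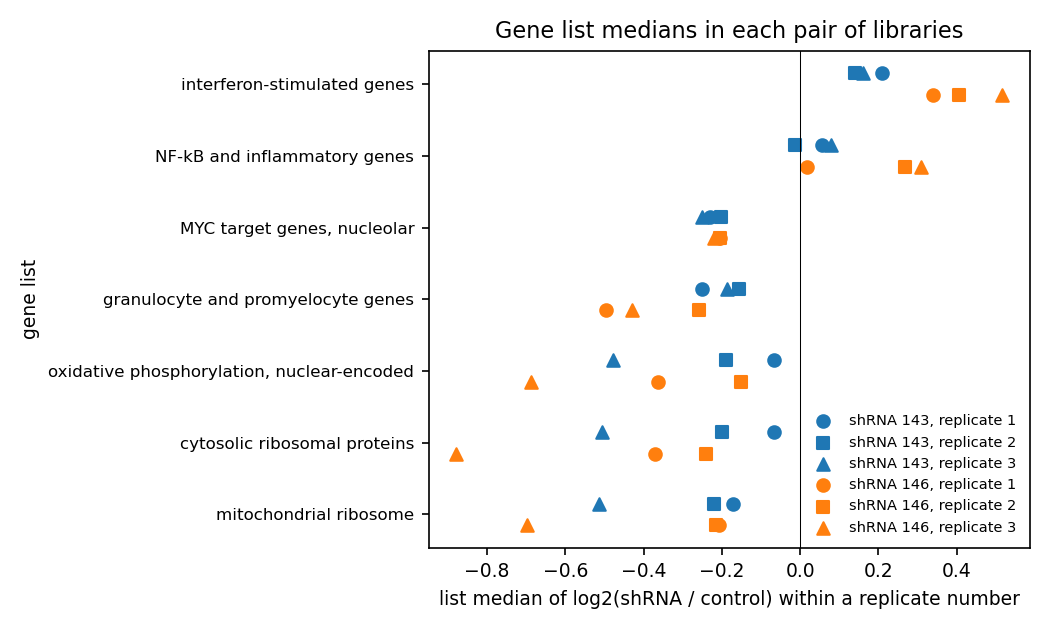
Median log2 ratio of shRNA to control library within a replicate number, for the 7 gene lists that passed camera without the block, by shRNA (colour) and replicate number (shape). Medians ran from -0.88 to -0.07 for ribosomal proteins, from -0.70 to -0.17 for the mitochondrial ribosome and from 0.14 to 0.52 for interferon-stimulated genes.

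Lists tied to NFATC2 and to the MLL fusion did not pass as sets. Of 36 NFAT and calcineurin pathway genes, 1 rose and 1, NFATC2 itself, fell, with 2 up and 1 down adjusted over the list alone, and the calcium sensor STIM2 rose by 0.60 ± 0.14 (camera adjusted p = 0.180). Most classical NFAT target genes on the fixed list had counts too low to be tested. Of the 9 tested, 0 passed by edgeR in either fit, with 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (camera adjusted p = 0.577). Of 36 KMT2A fusion target genes, 2 rose and 1 fell, with 3 up and 1 down adjusted over the list alone (adjusted p = 0.392). CPEB2 rose by 0.83 ± 0.13 and ZEB2 by 0.62 ± 0.14, and LMO2 fell by 0.81 ± 0.11, with -1.75 ± 0.13 for shRNA-143 and 0.13 ± 0.13 for shRNA-146. HOXA9 was at 0.05 ± 0.13 (adjusted p = 0.835) and MEIS1 at -0.19 ± 0.14 (adjusted p = 0.422), both homeobox factors that the fusion keeps high.

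The lists of CDK inhibitors and G1 cyclins and of p53 targets did not pass as sets. Of 21 CDK inhibitor and G1 cyclin genes, 4 rose and 0 fell, in the same numbers adjusted over the list alone: BTG2 by 1.18 ± 0.20, CDKN1A, which encodes p21, by 0.95 ± 0.19, CDKN1B, which encodes p27, by 0.71 ± 0.11, and CCNE2, a cyclin that drives S phase entry, by 0.70 ± 0.17. CDKN1A was at 0.43 ± 0.22 with shRNA-143 and rose by 1.47 ± 0.22 with shRNA-146. The list median was -0.01 and its mean 0.12 (camera adjusted p = 0.400). Of 28 p53 target genes, 3 rose and 1 fell, with 5 up and 1 down adjusted over the list alone, and the median was -0.05 and the mean 0.13 (adjusted p = 0.447). Library size scaling turned the sign of both lists' medians, to 0.10 for the CDK inhibitor list and 0.07 for the p53 targets. POLH rose by 0.59 ± 0.14, and GDF15 stood at 1.73 ± 0.48 (adjusted p = 0.0603). Of the list members named, RPS25, MRPL34, MRPS12, MRPL2, ATP5ME, COX7C, NOP16, IRF1, BCL3, CPEB2, ZEB2, HOXA9, MEIS1, CDKN1A, CCNE2 and POLH overlap other genes, with the same limit on their counts.

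The shRNAs were then compared with each other. SHISA5, ETFRF1, ADGRE5, UBE2F, CPEB3 and LMO2 were lower with shRNA-143 than with shRNA-146, with differences of shRNA-146 against shRNA-143 of 2.66 ± 0.16, 2.83 ± 0.25, 2.08 ± 0.19, 2.04 ± 0.25, 1.91 ± 0.19 and 1.88 ± 0.13. ADGRE5 is the adhesion receptor CD97 and CPEB3 a translational regulator. Lower with shRNA-146 were SVIP at -1.39 ± 0.20, BTBD3 at -1.38 ± 0.14, SERPINB10 at -1.35 ± 0.23, the ubiquitin-conjugating enzyme UBE2W at -1.34 ± 0.14 and EXOSC1 at -1.29 ± 0.17, with adjusted p-values of at most 0.0205. RRM2, the ribonucleotide reductase subunit, and the chaperone HSP90AB1 also differed, by 1.45 ± 0.15 and 0.87 ± 0.14. SERPINB10 overlaps SERPINB2, and ETFRF1, ADGRE5, UBE2F, SVIP, BTBD3, UBE2W and RRM2 also overlap other genes, which leaves their counts uncertain.

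Between the shRNAs, 179 genes passed with the block, 116 higher with shRNA-146 and 63 lower, and 7 without it, 7 higher and 0 lower, with 561 at an unadjusted p under 0.05. With the block the count without replicates 1, 2 and 3 of shRNA-143 was 31, 34 and 41, of shRNA-146 344, 61 and 172, and of control 135, 70 and 136, and in the same order without the block 3, 0, 0, 8, 2, 5, 3, 3 and 2.

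Certain short words were frequent in the 3' UTRs of these genes, in a scan chosen after the data were seen. The word GTTGTGT, which occurs in an NFATC2 transcript, was carried by 65.4% of the scanned genes that were lower with shRNA-143 than with shRNA-146, against 14.8% of all 9454 scanned genes. The word ATGAGTA, also in an NFATC2 transcript, was carried by 59.6% of those lower with shRNA-146, against 10.2%. Both words were chosen over all replicates as those with the highest and lowest scores for shRNA-146 against shRNA-143, in the same fold changes, which by itself favours a high share, and chosen in replicate 1 alone the words were GTTGTGT and TGAGTAA. Of genes that fell with shRNA-143 against control, 99 of 216 with a 3' UTR, or 45.8%, carried GTTGTGT, against 13.8% of those tested, and of genes that fell with shRNA-146, 73 of 269, or 27.1%, carried ATGAGTA, against 9.64%. SHISA5, ETFRF1, DGUOK, ELL2, LMO2, ADGRE5, CPEB3, EXOSC6, RAC3 and DHCR7 carried GTTGTGT, SVIP, DNAJC19, UBE2W and CD59 carried ATGAGTA, and TSN and BTBD3 both, while UBE2F, EXOSC1, SERPINB10, COMTD1, HSH2D, PSTPIP1, C1RL, SPNS3, MSRB1 and EEF1AKMT4 carried neither.

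**Figure D4:**
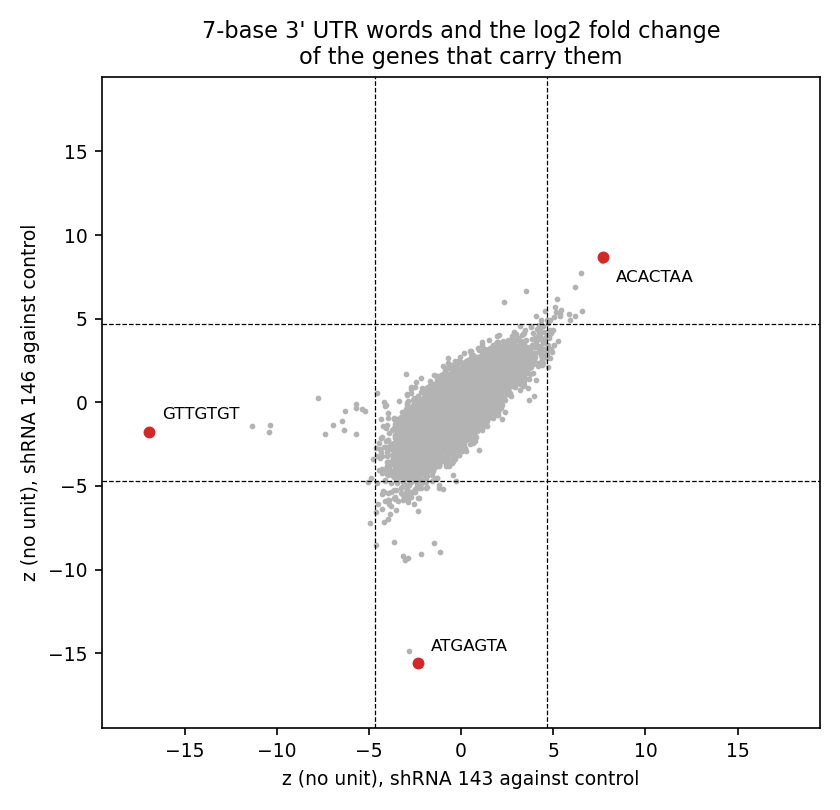
Score z of each of 16284 words of 7 bases for the log2 fold changes of genes that carry it, with shRNA-143 (horizontal axis) and shRNA-146 (vertical axis); dashed lines mark the permutation bound of 4.68. GTTGTGT lies at -16.9 with shRNA-143 and -1.76 with shRNA-146, ATGAGTA at -2.32 and -15.6, and ACACTAA above the bound with both.

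The authors' deposited tables passed 139 genes for shRNA-143, 50 up and 89 down, and 60 for shRNA-146, 36 up and 24 down, at an adjusted p under 0.05. In the authors' deposited tables, 27 genes passed for both in the same direction and 0 in opposite ones. Of the 138 and 60 tested here, 130 and 60 passed with the block, and 7 and 5 without it. The authors' deposited table gave SHISA5 a log2 fold change of -2.90 (adjusted p = 9.63e-26) and NFATC2 -2.07 (adjusted p = 0.0206) with shRNA-143, and that for shRNA-146 gave NFATC2 -1.84 (adjusted p = 0.0398).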

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

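The tests of a 3' UTR match, knockdown depth, length and GC content and the state of the controls were chosen after the results were seen, and the splits of the libraries before. Without the block, edgeR's test of shRNA-146 against shRNA-143 set apart SHISA5 (a log2 difference of 2.65), PPP1R14C (3.28), LMO2 (1.88), ADGRE5 (2.10), CPEB3 (1.90), NECAP1 (1.87) and ETFRF1 (2.87), with adjusted p-values from 0.00464 to 0.0249. PPP1R14C and NECAP1 are named because they passed, after their values were seen. In 7 lists, the shRNAs' effects also differed by camera: oxidative phosphorylation (median difference -0.16, adjusted p = 0.000918), mitochondrially encoded genes (-0.30, 0.00297), cytosolic ribosomal proteins (-0.24, 3.46e-08), monocyte and macrophage maturation (0.20, 0.00522), interferon-stimulated genes (0.16, 0.00297), heat shock (0.15, 0.0311) and lysosome genes (0.10, 0.0452). With an estimated correlation none of the 7 passed, with adjusted p = 0.652 to 0.887. With the block edgeR passed 2 heat shock and 2 lysosome genes over all genes, and 2 heat shock, 4 lysosome and 2 interferon-stimulated genes adjusted over the list alone.

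For the genes that differed between the constructs, a deeper knockdown by shRNA-143 needs most of the 179 to lie further from control with it, but 51.4% did. The upper bound of 58.9% counts genes as independent, which they are not, so it does not measure the spread between libraries. An origin in length and GC content needs calls lost after correction, but 99.4% of the 179 still passed. The correction also lowered the common dispersion from 0.0313 to 0.0179 and raised the calls to 580, which favours passing. The share that passed is therefore a weak test of length and GC content. A candidate explanation is silencing of other mRNAs through a short 3' UTR match to each construct: the words picked in replicate 1 alone, GTTGTGT and TGAGTAA, had absolute z-scores of at least 13.3 in replicates 2 and 3, against a bound of 4.68. Whether these words are part of the shRNAs stays open, since the shRNA sequences were not used here. TGAGTAA does not occur in NFATC2, but it shares the bases TGAGTA with ATGAGTA, which does. How often words of 7 bases occur by chance in the full NFATC2 transcripts was not tested.

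Lower ribosomal, mitochondrial ribosome and oxidative phosphorylation transcripts lay on short genes. After correction for deposited gene length and GC content, the mean list medians over the 3 replicate numbers were -0.33 (SD 0.22), -0.25 (SD 0.16) and -0.26 (SD 0.19). The fitted trend in those measures alone therefore does not account for them. The lengths of the transcripts that these cells express were not used, so a trend in them stays open. After this correction with the block, camera with an estimated correlation passed 0 lists for the mean of both shRNAs. A state of the control libraries that both comparisons share cannot be told apart from an effect of both shRNAs: the medians of shRNA-146 minus shRNA-143, which use no control library, were -0.24 (SD 0.17), -0.051 (SD 0.078) and -0.15 (SD 0.16), and the controls are in both comparisons. An effect of NFATC2 on these lists stays open as well.

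Other splits of the same libraries were also counted. For shRNA-143, shRNA-146 and shRNA-146 against shRNA-143 the 10 splits are too few for a share under 0.05, with real counts of 7, 5 and 7 and the highest other 0, 1 and 0, and so are the 4 paired splits, with real counts of 474, 662 and 179 and the highest other 0 each; 1 of the splits reached the count each time, the real one. For both shRNAs against control as 1 group, 5 of 84 splits gave as many genes as the real count of 1, so chance is not excluded; the highest, 6189, put the libraries numbered 1 together, which points to a structure of the libraries. With the block the real count was 400, reached by 1 of 27 splits, the smallest share that they allow. The other splits with any genes put shRNA-143 (46) or shRNA-146 (35) whole in the place of control. Splits that mix the groups turn differences between groups into residual spread, so these splits cannot exclude chance for that count. For genes passing with both, 2 of 100 splits reached the count of 1, again led by the libraries numbered 1 at 3649. These splits mix the replicate numbers, and the count fell to 0 without 1 library in 7 of 9 cases, so chance is left open for it. With the block 1 of 100 reached 200, the highest other being 72 with shRNA-143 whole in the place of control. The same limit holds there, so chance is left open for that count too. For the lists in that fit of 1 shRNA group, 38 of 84 splits reached 6 passing lists (highest 13), and 13 of 27 with the block reached 6 (highest 12), so chance is not excluded for the list results.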

How the results depend on the processing

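Alternatives chosen after the data were seen were the length and GC correction, leaving out the libraries numbered 1, and all alternatives of the fit with the replicate block. Named genes kept their direction in 125 of 125 comparisons that passed with the block. Of these, 81 passed in every setting with the block that left out no replicate. Those settings include the fit of only the groups compared, which uses fewer than 9 libraries for a pair of groups and in which 35 fell short. In every setting but the fit without the block, 29 passed. The counts of 7, 5, 5, 7 and 1 genes (shRNA-143, shRNA-146, mean of both, shRNA-146 against shRNA-143, same direction with both) became, with the replicate block, 474, 662, 859, 179 and 200, with DESeq2 151, 162, 203, 89 and 52, with only the groups compared 1, 0, 1, 0 and 0, with the length and GC correction 39, 18, 36, 37 and 7, with that and the block 1486, 1710, 2218, 580 and 645, and without the libraries numbered 1 589, 951, 1525, 160 and 291. Library size scaling gave 16 for shRNA-143, 2 for shRNA-146 and 2 for both, median-of-ratios scaling 3 for shRNA-146, and the stricter filter 12 for shRNA-143 and 3 for both. Leaving out 1 library at a time gave 1 to 28, 0 to 3, 0 to 5, 0 to 8 and 0 to 3. The cause was not tested. Fewer libraries or groups leave fewer degrees of freedom, which does not account for the counts that rose.

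In the fit with the replicate block, the counts of 474, 662, 859, 179 and 200 became 1240, 1653, 1946, 436 and 568 with no filter on low counts, 1001, 1400, 1642, 374 and 464 with DESeq2, 1575, 2111, 2902, 319 and 873 without the libraries numbered 1, 1486, 1710, 2218, 580 and 645 with the length and GC correction, and 164, 181, 140, 65 and 47 at an absolute log2 fold change of at least 1. With only the groups compared they were 2789, 217, 400 and 53, where a fit of a pair of groups had 2 residual degrees of freedom. Without a filter on low counts the prior degrees of freedom were infinite, so those counts are unreliable. Leaving out 1 library gave 55 to 2099, 27 to 1745, 14 to 3075, 31 to 344 and 11 to 878. The highest count of each came without shRNA-146 replicate 1, where the common dispersion went from 0.0313 to 0.0162. That library had the fewest genes with a count, 18485, and the largest length and GC trend (SD 0.487 in log2 units).

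NFATC2 passed with the block (-2.27 and -1.96), with the length and GC correction and the block (-2.41 and -2.12) and without the libraries numbered 1 (-1.93 and -1.77), and not without the block in all 9 libraries by edgeR (-2.09 and -1.85), DESeq2 or limma-voom. Leaving out 1 library gave -2.41 to -1.65 and -2.27 to -1.48, and with the block -2.52 to -2.02 and -2.15 to -1.69. The correlation between shRNAs was 0.546 and 0.552 with the block without a filter, and 0.519 to 0.826 and 0.512 to 0.781 without 1 library. Passing lists, 7 without and 6 with the block, became 11 and 11 without a filter, 11 and 11 without the libraries numbered 1, 10 with the block and length and GC correction, 0 and 0 with an estimated correlation, 0 without the block by fry, and 5 to 11 and 6 to 10 without 1 library. In the fit with the block, HOXA9 ran from -0.043 without control replicate 2 to 0.16 without control replicate 3, and MYC turned to 0.029 with library size scaling. Low counts limit genes such as BIRC3, at 0.129 CPM in control. In data simulated for shRNA-143 under the model of the fit with the block, log2 changes of 1 were found in 0.205% of changed genes without the block and 66.0% with it.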

Other observations

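Other genes changed for the mean of both shRNAs, in lists that did not pass as sets. In the cholesterol lists, SC5D rose by 0.81 ± 0.12 while DHCR7 fell by 1.13 ± 0.11, both of the last steps of synthesis, and the exporter ABCA1 rose by 0.89 ± 0.18, with 0.43 ± 0.21 for shRNA-143 and 1.36 ± 0.21 for shRNA-146. The calprotectin genes S100A8 and S100A9 fell by 0.71 ± 0.15 and 0.70 ± 0.14 and the receptor FPR2 by 0.95 ± 0.17, while SIGLEC1 rose by 1.27 ± 0.26, so that 3 monocyte and macrophage genes rose and 4 fell of 46 tested, against 10 and 5 adjusted over the list alone (camera adjusted p = 0.180). The lipoprotein receptor VLDLR rose by 0.95 ± 0.15 and the cystine transporter SLC7A11 by 0.92 ± 0.15, with DDIT3 up by 0.49 ± 0.12 and SLC7A1 down by 0.48 ± 0.11 among 36 integrated stress response genes, of which 3 rose and 1 fell, against 4 and 1 adjusted over the list alone (adjusted p = 0.266). The glucose transporter SLC2A1 fell by 0.62 ± 0.10, the only 1 of 25 glycolysis genes to pass over all genes. In the cell cycle lists AURKA fell by 0.41 ± 0.10, CDCA8 by 0.46 ± 0.11, RRM2 by 0.48 ± 0.12 and CHAF1B by 0.45 ± 0.11, and PIMREG rose by 0.86 ± 0.19, while AURKB stood at -0.49 ± 0.13 (adjusted p = 0.0519). The changes of the mean of both shRNAs passed edgeR's test with the block, AURKB's excepted, and none passed without it. RRM2 differed between the shRNAs, with -1.21 ± 0.15 for shRNA-143 and 0.24 ± 0.14 for shRNA-146. SLC7A11, VLDLR, DDIT3, SLC2A1, RRM2, CHAF1B and PIMREG overlap other genes, as do the list members NPC1, SNHG5, LIN28B, KRT8 and PAX5, so their counts are uncertain.

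Counts up and down with the block, over all genes and then adjusted over the list alone, were 1 and 2, then 1 and 2, of 60 G1/S genes; 2 and 3, then 3 and 6, of 64 G2/M genes; 1 and 0, then 1 and 0, of 24 MYC and E2F genes, where E2F7 rose by 0.58 ± 0.14; and 0 and 1, then 1 and 1, of the glycolysis genes. They were 1 and 1 in both of 24 cholesterol synthesis genes, 1 and 0, then 2 and 1, of 10 LXR targets, 1 and 0, then 0 and 0, of 33 immediate early genes, where FOSL2 rose by 0.65 ± 0.16, and 1 and 0 in both of 25 unfolded protein response genes, where ERO1B rose by 0.75 ± 0.13. Of 17 heat shock genes 1 rose and 1, HSP90AB1, fell by 0.65 ± 0.12 (-1.08 ± 0.14 for shRNA-143 and -0.21 ± 0.14 for shRNA-146), then 1 and 2, of 17 BCL2 family genes BIK fell by 0.48 ± 0.11 in both, and of 32 lysosome genes 2 rose and 0 fell in both, among them NPC1 by 0.50 ± 0.12. By edgeR, 0 of 13 mitochondrially encoded, 12 stem and progenitor and 14 MHC class II genes passed in either fit, over all genes and adjusted over the list alone, against 2, 3 and 3 at an unadjusted p under 0.05 with the block and 0, 0 and 1 without it. By limma-voom 0 passed in either fit, and by DESeq2 1 MHC class II gene with the block. Of lists that read RNA selection, HIST1H2AC rose by 0.97 ± 0.23 of 18 histone genes, and SNHG5 fell by 0.49 ± 0.13 of 21 nuclear RNAs. Camera passed none of these lists with the block, at adjusted p-values from 0.0742 to 0.859.

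Of 11 markers of the 293T cells that made the virus, all of which passed the filter on low counts in these libraries, the median was 0.28 with the block and 0.40 with library size scaling too. Among them LIN28B rose by 0.65 ± 0.14 (85.9 CPM in control) and KRT8 stood at -0.60 ± 0.16 (adjusted p = 0.0583), with 1 up and 0 down over all genes and 1 and 1 adjusted over the list alone (camera adjusted p = 0.400). NKG7 fell by 0.74 ± 0.16 of 4 T and natural killer cell markers and PAX5 rose by 0.93 ± 0.21 of 4 B cell markers, lists too short for a set test, and 0 of 5 erythroid and megakaryocyte markers passed by edgeR, DESeq2 or limma-voom in either fit, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.526).

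Of the words scanned in 3' UTRs, 54 lay beyond the bound of 4.68 downward for the mean of both shRNAs, led by GTTGTGT at -10.6, and 37 upward, a pattern for which the test of the control construct was chosen after the result was seen, and those of microRNA families and of length and GC content before. The 997 of 9454 genes that carry ACACTAA had a median log2 fold change of 0.16, against -0.01 in the others. Unlike the z, these medians do not allow for length, and the longest bin of all genes had a median of 0.19 and the shortest of -0.22. The word had the highest z, 8.61, followed by the overlapping AACACTA among its anagrams at 8.46, and a z of 8.998 after length and GC correction. The score already allows for gene length and the GC content of the 3' UTR, so that correction is a weak test of the trend. Sites of 20 microRNA families that blood cells express had a mean z of 1.23 against 0.559 for 20 families of other tissues. The difference was 0.673 (SE 0.529, two-sided permutation p = 0.214). By the rule set beforehand, a p this high with a difference this small counted against relief of such sites. That rule took no account of the SE. The SE and p treat the sites as independent, though some share bases and all were scored on the same genes. Relief of such sites may thus or may not play a part. Silencing by the control construct may also explain the rise of genes with ACACTAA, since the word's z for shRNA-146 against shRNA-143 was 1.52. Any effect that both shRNAs share would give the same value, however, and the cause stays open.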
